A study of Arabidopsis thaliana with 6 samples.

How the data were processed

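RNA was sequenced from Arabidopsis thaliana seedlings harvested after 4 days in the dark at 22 °C, following stratification for 3 days at 4 °C and 12 h of white light. The labels give 3 genotypes with 2 biological replicates each, so 6 libraries. Col is the wild type, f1f3 is the double mutant of FYPP1 and FYPP3, and pifq is the quadruple pif mutant, whose genotype label is misspelled and was read as pif1 pif3 pif4 pif5. The p-values below measure the spread between libraries of separate biological replicates.

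Per the labels, the authors used Trimmomatic, TopHat2 2.1.0, HTSeq 0.6.1 and edgeR with the TAIR10 build, without a statement of which step made the deposited values. Each library has 1 deposited file of 24439 genes with a signal value written to 1 decimal. Between 99.98% and 100% of the values in each library were whole multiples of a library-specific number, within a tolerance of 0.0505. That number, the value of 1 read, ranged from 0.799 to 1.29. Its product with the library's median-of-ratios size factor was 1.0 in all 6 libraries, so the deposited signal equals gene counts divided by that factor. The reads recovered in this way came to 17.9 M and 23.8 M for the Col libraries, 20.2 M and 21.6 M for f1f3, and 27.7 M and 19.4 M for pifq.

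The test of each comparison was limma 3.58.1 with an intensity trend on log2 of the deposited value plus 1, two-sided, with all 6 libraries in 1 fit. Genes with a value of at least 10 in at least 2 libraries were tested, which left 20581. The Benjamini-Hochberg adjusted p threshold was 0.05, and the fit had 3 residual and 5.15 prior degrees of freedom. The planned test had been the edgeR quasi-likelihood test on raw counts. Because the files hold scaled values, limma took its place, and edgeR 4.0.16 with TMM factors on the recovered reads became an alternative chosen after the files were seen. The fits with edgeR and other factors, or with DESeq2, had been planned and were likewise run on the recovered reads.

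The comparisons, the gene lists, the rule for naming genes and most alternatives were fixed before the data were examined. The rule names the 6 targeted genes, the 8 largest rises and 8 largest falls per mutant, up to 4 members of each list with the smallest p, 5 per direction between the mutants, and 6 per direction shared by both. Genes for the largest changes needed an average log2 CPM of at least 2, a symbol and no overlap between the libraries of the compared groups. No gene named below as risen or fallen had such an overlap.

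The 26 gene lists held 414 distinct genes, of which 4 (F3H, BAN, BBX30 and PDF1.2) were not in the files. None was dropped, and 6 were kept because the description in the name table fitted. The 25 lists with at least 5 tested members were tested with camera at a preset correlation of 0.01, again with an estimated correlation, and with fry. Of the 75 list tests, 35 passed with the preset correlation and 0 with the estimated correlation. The lowest adjusted p with an estimated correlation was 0.357. That test draws on the 3 residual degrees of freedom of the fit, so a list that fails it is not thereby shown to be unchanged. The estimates ran from -0.0298 for circadian clock genes to 0.885 for seed storage genes. They were 0.577 for antenna, 0.856 for photosystem, 0.603 for Calvin cycle, 0.254 for chlorophyll and 0.00334 for carotenoid genes. Where members vary together more than the preset of 0.01 allows, camera with the preset gives too small a p. The 4 further lists, 2 of glucosinolate biosynthesis, 1 of sugar starvation and 1 of jasmonate biosynthesis, were written after the largest changes had been seen, and left out the genes that prompted them.

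The overlap between the mutants was set against independent lists and against 50 simulated sets of unchanged groups that share the Col libraries. The fits were tested on simulated data with known changes in 20537 genes. There limma recovered 20% of genes changed 2-fold and 93.2% of those changed 4-fold in f1f3 against Col, and 12.6% of its calls were false. In pifq against Col it recovered 21.2% and 93.2%, with 9.42% false, and in pifq against f1f3 12.4% and 95.6%, with 12.6% false. Each comparison was simulated from the same means, spread and changed genes, 250 per fold summed over 5 draws. Differences between these rates therefore do not reflect the genotypes. In every comparison the false share, 9.42% to 12.6%, was above the share of 0.05 that the adjusted p threshold aims at. Limma thus did not hold that threshold in the simulation. Far more genes were called in the data, and the adjusted p depends on that number, so the recovery rates do not carry over. The false share among the genes called in the data was not measured. The counts of changed genes below are therefore not shown to be held at 0.05. For genes with at most 3 reads in a group, the ratio of reads has an exact 95% interval that covers counting error only.

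Alternatives were edgeR with TMM factors, RLE factors or library totals, DESeq2 1.42.0, limma with TMM or library totals, 2 other pseudocounts, 2 other filters, nuclear genes alone, only the 4 libraries compared, stricter thresholds, the replicate number as a block, and each library left out in turn. With a library left out, its group has 1 library, which is assumed to vary like the others. That group then holds a single replicate number, so the pattern left by replicate numbers, described below, can enter its comparisons. With 2 libraries per group, no test of single outlying libraries and no count of other splits was made. No library was left out of the reported values.

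Gene names came from an annotation of the TAIR10.1 assembly, which differs from the build of the labels, so no positions are given. It matched 24148 of the genes and gave a symbol for 9760. R 4.3.3 and Python 3.11.15 with matplotlib 3.10.9 were used.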

Results

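The series asks how PP6 phosphatases and PIF proteins act on seedling development in the dark. FYPP1 and FYPP3 are catalytic subunits of the protein phosphatase PP6, and the PIFs are transcription factors that restrain light-type development in darkness. Gene expression was measured by RNA-seq in 4-day-old dark-grown seedlings of Col, f1f3 and pifq, with 2 libraries per group and 17.9 to 27.7 M recovered reads per library. Values below are deposited values, that is reads scaled per library, as mean ± SD with n = 2. Every gene said to have risen or fallen lay on the same side in both libraries of the group. Principal component 1 (46.5% of the variance) set f1f3 apart from the other groups, and component 2 (26.3%) set pifq apart from Col. Transcripts of 15 seed storage and late embryogenesis genes took 0.0961% of the reads of pifq replicate 1 and at most 0.00115% of those of any other library.

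The mutated genes differed in how far their transcripts were reduced. In f1f3, FYPP1 (AT1G50370) fell from 735 ± 33.1 in Col to 336 ± 71.5 (log2 fold change -1.14, SE 0.21, limma adjusted p = 0.00846), and FYPP3 (AT3G19980) fell from 590 ± 9.5 to 272 ± 17.7 (-1.11, SE 0.19, adjusted p = 0.00737). In pifq, PIF3 (AT1G09530) fell from 1868 ± 130 to 49.9 ± 17.5 (-5.24, SE 0.24, adjusted p = 4.6e-05) and PIF5 (AT3G59060) from 565 ± 134 to 114 ± 36.6 (-2.32, SE 0.34, adjusted p = 0.00932). PIF1 (AT2G20180) stood at 866 ± 33.5 in Col and 1189 ± 41.2 in pifq (adjusted p = 0.125), and PIF4 (AT2G43010) at 452 ± 35.1 and 857 ± 251 (adjusted p = 0.0808). In f1f3, PIF4 fell to 102 ± 19.5 (-2.15, SE 0.26, adjusted p = 0.00277) and PIF5 to 264 ± 101 (-1.13, SE 0.34, adjusted p = 0.0458), while PIF3 (-0.36, adjusted p = 0.317) and PIF1 (0.18, adjusted p = 0.438) did not pass. FYPP1 and FYPP3 did not pass in pifq (-0.09 and -0.23). As a list, 4 of the 6 targeted genes fell in f1f3 and 2 in pifq, and adjusted over the list alone 4 fell in f1f3, and 2 rose and 2 fell in pifq. The camera test of the list passed in f1f3 (adjusted p = 0.0125) but not with an estimated correlation (adjusted p = 0.456 with an estimated correlation), and it did not pass in pifq (adjusted p = 0.184). Since the list holds the genes mutated in each mutant, the design can bring about part of these list results. Without f1f3 replicate 2 the adjusted p was 0.0547 for FYPP1 and 0.234 for PIF5 in f1f3, which was 0.21 without Col replicate 2, 0.0677 without Col replicate 1 and 0.0569 with library totals. PIF5 in pifq had 0.0523 without Col replicate 2 and 0.0583 without pifq replicate 1.

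**Figure D1:**
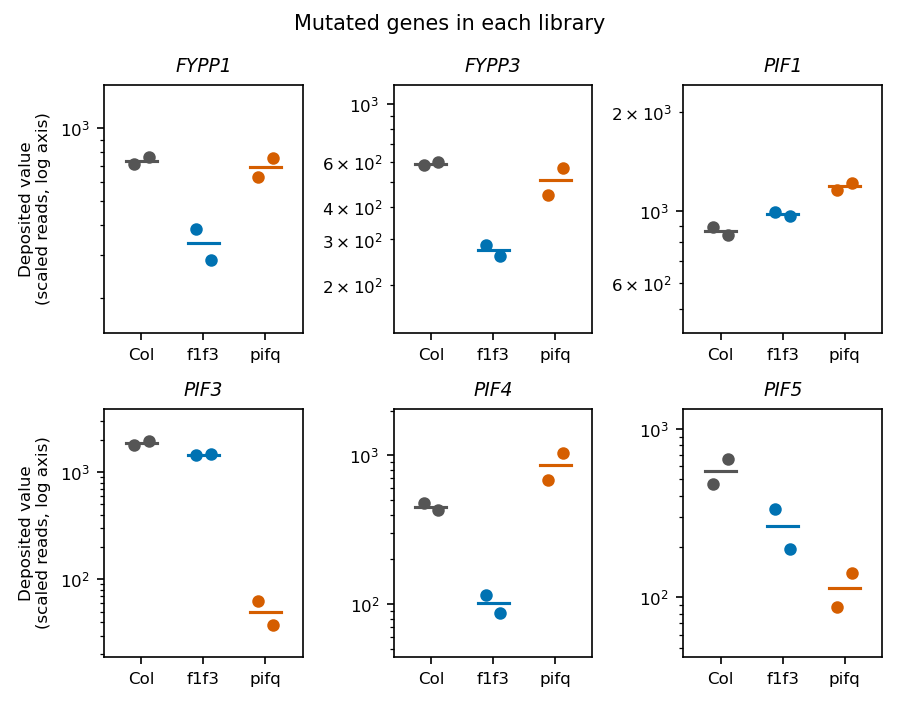
Deposited values (scaled reads, log axis) of the mutated genes in each library, where points are libraries and lines are group means. PIF3 stood at 49.9 in pifq against 1868 in Col, and PIF1 at 1189 against 866.

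Most antenna, photosystem and Calvin cycle transcripts were lower in f1f3 than in wild-type seedlings. Of 20 light-harvesting antenna genes, which encode the chlorophyll-binding proteins around the photosystems, 19 fell and 1 did not pass (20 fell adjusted over the list alone), with a median log2 fold change of -2.71. LHCA1 (AT3G54890), an antenna protein of photosystem I, fell from 5766 ± 908 to 1113 ± 423 (-2.42, SE 0.30, limma adjusted p = 0.00305). LHCB2.1 (AT2G05100) and LHCB1.4 (AT2G34430) fell, at -3.53 and -3.43 on the log2 scale. Near-identical copies of these families can share reads, which was not measured, so values of single copies are uncertain. Of 26 nuclear genes for photosystem subunits (23) and for the electron carriers between the photosystems, PETC (AT4G03280), PETE1 (AT1G76100) and PETE2 (AT1G20340), together called photosystem genes here, 25 fell (26 adjusted over the list alone; median -1.96), among them PSBO2 (AT3G50820) of the oxygen-evolving complex, from 2632 ± 107 to 572 ± 132 (-2.22, SE 0.20, adjusted p = 0.00137). PSBQ-2 (AT4G05180) fell by 2.76 and PSAK (AT1G30380) by 2.67. Of 19 Calvin cycle genes 13 fell (16 adjusted over the list alone; median -1.45), such as PRK (AT1G32060), phosphoribulokinase, from 18787 ± 1032 to 4606 ± 1399 (-2.06, SE 0.27, adjusted p = 0.00331). RBCS1B (AT5G38430), a copy of the Rubisco small subunit whose reads can be shared with other copies, fell by 2.50. Of 26 chlorophyll biosynthesis genes 9 fell (9 adjusted over the list alone; median -0.30), including CHLH (AT5G13630), a magnesium chelatase subunit, from 14876 ± 4104 to 4633 ± 429 (-1.66, SE 0.28, adjusted p = 0.00685). Of 12 carotenoid biosynthesis genes 4 fell (5 adjusted over the list alone; median -0.46), led by ZEP (AT5G67030) at -1.19. The camera adjusted p of these 5 lists was 5.4e-13, 2.3e-13, 1.9e-08, 0.00115 and 0.00375. In the same order it was adjusted p = 0.45, 0.456, 0.456, 0.468 and 0.45 with an estimated correlation, and fry did not pass for photosystem or chlorophyll genes (adjusted p = 0.0556 for both). Without f1f3 replicate 2, 13 photosystem, 6 Calvin cycle, 1 chlorophyll and 1 carotenoid gene fell. Without Col replicate 2, 8 Calvin cycle, 1 chlorophyll and 2 carotenoid genes fell, and without Col replicate 1, 4 chlorophyll and 2 carotenoid genes fell.

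Cell cycle transcripts were higher in f1f3. Of 14 cell cycle genes 13 rose (13 adjusted over the list alone; median 1.19), among them MCM5 (AT2G07690), a subunit of the replicative helicase, from 384 ± 16.3 to 961 ± 223 (1.3, SE 0.21, limma adjusted p = 0.00579). HIK (AT1G18370), a cytokinesis kinesin, rose from 249 ± 19.9 to 595 ± 120 (1.24, SE 0.20, adjusted p = 0.00597), and CYCA1;1 (AT1G44110) rose by 1.47. Camera gave the list an adjusted p = 2.6e-07, and adjusted p = 0.45 with an estimated correlation. Among 14 root cell markers in the same seedlings 4 rose and 1 fell (5 and 2 adjusted over the list alone). EXPA18 (AT1G62980), a root hair expansin, rose from 223 ± 57.2 to 1148 ± 21.4, and IRT1 (AT4G19690), the iron transporter of the root epidermis, fell from 969 ± 978 to 11.5 ± 15.1. The median of the root markers was -0.09 and turned positive with library totals. Without Col replicate 1, Col replicate 2 or f1f3 replicate 2, the cell cycle genes that rose numbered 8, 4 and 4, and the changed root markers 2, 3 and 2.

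Several hormone and growth groups also held genes that fell in f1f3. Of 16 abscisic acid response genes 7 fell (8 adjusted over the list alone; median -1.02), such as COR47 (AT1G20440), a dehydrin, from 15238 ± 2476 to 3377 ± 806 (-2.18, SE 0.24, limma adjusted p = 0.00241). Of 27 shade and PIF-induced genes 8 fell (9 adjusted over the list alone; median -0.47). HFR1 (AT1G02340), a transcription factor that antagonises PIFs, fell from 706 ± 55.6 to 244 ± 7.8 (-1.53, SE 0.21, adjusted p = 0.00391), whereas PIL1 (AT2G46970) stood at 1227 ± 40.0 in Col and 1465 ± 75.9 in f1f3. Of 13 gibberellin genes 6 fell (6 adjusted over the list alone), with GASA6 (AT1G74670) at -2.49, and of 14 ethylene and apical hook genes 5 fell (5 adjusted over the list alone), with the ethylene-forming oxidase ACO4 (AT1G05010) at -1.82. Of 35 auxin response genes 5 fell (1 adjusted over the list alone). Of 24 cell wall expansion genes 1 rose and 7 fell (1 and 7 adjusted over the list alone), XTH24 (AT4G30270) by 3.12 and XTH30 (AT1G32170) by 1.78, while XTH16 (AT3G23730) rose by 1.3. With library totals 1 auxin response gene rose and 1 fell and 3 ethylene genes fell, and with DESeq2 1 auxin response gene rose and 7 fell. Camera adjusted p was 0.000906, 0.00796, 0.0255, 0.00848, 0.000162 and 0.03 for the lists in this order, and adjusted p = 0.45, 0.468, 0.594, 0.45, 0.468 and 0.594 with an estimated correlation. Fry did not pass for abscisic acid (0.0556), shade (0.0624), gibberellin (0.164), auxin response (0.0624) or cell wall genes (0.164). In the same order, the changed genes numbered 3, 3, 1, 1, 1 (a rise) and 4 without f1f3 replicate 2, and 3, 4, 2, 2, 1 and 5 without Col replicate 2. They numbered 5, 3, 1, 1, 0 and 4 without Col replicate 1, auxin response 8 and ethylene 3 without f1f3 replicate 1, and camera did not pass for gibberellin or cell wall without f1f3 replicate 2 (0.133 and 0.154) or Col replicate 1 (0.0697 and 0.221).

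Among the genes picked by the naming rule, the largest falls in f1f3 were steeper than the largest rises. The rule leaves out genes without a symbol or with a low average over all libraries, which a gene high only in f1f3 can have. Changes outside it include a rise of NDB4 (AT2G20800) by 4.35 and a fall of AT3G28915 at -10.74. ASN1 (AT3G47340), an asparagine synthetase, fell from 9327 ± 835 to 235 ± 265 (-6.01, SE 0.94, limma adjusted p = 0.00555), and XTH7 (AT4G37800) from 1512 ± 397 to 38.8 ± 1.0 (-5.22, SE 0.22, adjusted p = 5.9e-05). BCAT-2 (AT1G10070), TLL1 (AT1G45201), THA1 (AT1G08630), GRP9 (AT2G05440) and OCT1 (AT1G73220) fell, at log2 fold changes from -5.53 to -5.15, and IRT1 at -6.68. TYRDC (AT4G28680), a tyrosine decarboxylase, rose from 24.4 ± 11 to 361 ± 144 (3.85, SE 0.44, adjusted p = 0.00258). IMS2 (AT5G23020), an enzyme of methionine-derived glucosinolate synthesis, rose from 65.7 ± 3.7 to 603 ± 31.7 (3.18, SE 0.22, adjusted p = 0.000808), and IPMI2 (AT2G43100), CXE13 (AT3G48700) and NAC044 (AT3G01600) by 3.6, 3.39 and 2.95. CYP83A1 (AT4G13770), GPT2 (AT1G61800) and EXT6 (AT2G24980) rose by 3.80, 3.14 and 2.96. Of the 20581 genes tested, 2384 rose and 2634 fell, 3213 of them at least 2-fold. With library totals the median of all genes moved by 0.12 and the split was 2916 up and 2088 down, and the changed genes numbered 2610 without Col replicate 1, 1900 without Col replicate 2 and 1422 without f1f3 replicate 2. The adjusted p was 0.0821, 0.153 and 0.157 for CYP83A1, GPT2 and EXT6 without f1f3 replicate 2, 0.0607 and 0.125 for GPT2 and EXT6 without Col replicate 1, 0.0932 and 0.0567 without Col replicate 2, and 0.0842 for EXT6 without f1f3 replicate 1.

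In pifq, part of the antenna, photosystem and chlorophyll biosynthesis genes had higher transcripts than in wild-type seedlings, and few Calvin cycle or carotenoid genes changed. Of 20 antenna genes 11 rose and 9 did not pass (16 rose adjusted over the list alone; median 1.67), with LHCA1 (AT3G54890) at 5766 ± 908 in Col and 58656 ± 12086 in pifq (3.34, SE 0.30, limma adjusted p = 0.00134). LHCB1.4 (AT2G34430) rose by 6.30 and LHCB1.1 (AT1G29920) by 5.5, again uncertain for single copies. Of 26 photosystem genes 12 rose (23 adjusted over the list alone; median 1.47), such as PSBO2 (AT3G50820), from 2632 ± 107 to 10016 ± 553 (1.93, SE 0.20, adjusted p = 0.00236), and PSAN (AT5G64040), by 1.94. Of 26 chlorophyll biosynthesis genes 15 rose and 1 fell (20 and 1 adjusted over the list alone; median 0.93). CHLI1 (AT4G18480), a magnesium chelatase subunit, rose from 3458 ± 383 to 10082 ± 653 (1.55, SE 0.19, adjusted p = 0.00474), and the gene that fell was PORA (AT5G54190), the protochlorophyllide oxidoreductase of dark-grown seedlings, from 67811 ± 4460 to 9744 ± 92.4 (-2.80, SE 0.29, adjusted p = 0.00236). Of 19 Calvin cycle genes 2 rose and 1 fell (3 and 1 adjusted over the list alone), with GAPA-2 (AT1G12900), a glyceraldehyde phosphate dehydrogenase subunit, up by 1.88. Of 12 carotenoid genes 2 rose (2 rose and 1 fell adjusted over the list alone). Camera adjusted p was 2.8e-12 for antenna, 1.7e-15 for photosystem, 1.1e-09 for chlorophyll and 0.0439 for Calvin cycle genes, with adjusted p = 0.357, 0.357, 0.357 and 0.669 with an estimated correlation, and the carotenoid list did not pass (0.0967). Fry did not pass for antenna (0.0511), photosystem (0.0775) or Calvin cycle genes (0.378). The seed storage transcripts CRA1 (AT5G44120) and CRC (AT4G28520) stood at 8056 and 10170 in pifq replicate 1 and at 10.2 and 6.8 in pifq replicate 2. Without Col replicate 1, Col replicate 2, pifq replicate 1 or pifq replicate 2, the changed antenna genes numbered 6, 5, 5 and 5, photosystem genes 5, 4, 5 and 5 (22 and 20 without f1f3 replicate 1 or 2), chlorophyll genes 3, 6, 7 and 5, Calvin cycle genes 1 each and carotenoid genes 0, 2, 0 and 0 (1 and 1 without f1f3 replicate 1 or 2). With library totals 20 photosystem genes and 1 carotenoid gene rose, and with DESeq2 22 photosystem genes rose and 4 Calvin cycle genes rose and 1 fell. The Calvin cycle list had camera adjusted p = 0.132 without Col replicate 2 and 0.0603 without pifq replicate 1.

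Many shade and PIF-induced genes were lower in pifq. Of 27 such genes 12 fell (17 adjusted over the list alone; median -1.23). PIL1 (AT2G46970), a transcription factor of the shade response, fell from 1227 ± 40.0 to 14 ± 0.6 (-6.36, SE 0.19, limma adjusted p = 9.2e-06), HFR1 (AT1G02340) from 706 ± 55.6 to 42.0 ± 1.6 (-4.04, SE 0.21, adjusted p = 7.9e-05), and the wall enzyme XTH15 (AT4G14130) from 42922 ± 7856 to 818 ± 128 (-5.71, SE 0.30, adjusted p = 7.9e-05). Of 24 cell wall expansion genes 3 rose and 8 fell (3 and 9 adjusted over the list alone), with the expansin EXPA1 (AT1G69530) up by 2.03 and XTH31 (AT3G44990) and XTH5 (AT5G13870) at -1.79 and -2.13. Of 14 ethylene and apical hook genes 1 rose and 3 fell (1 and 7 adjusted over the list alone), including HLS1 (AT4G37580), which shapes the apical hook, from 919 ± 105 to 235 ± 84.0 (-2.00, SE 0.28, adjusted p = 0.00715), and ACS5 (AT5G65800), by 3.04. Of 18 light-signalling and early light-induced genes 2 rose and 7 fell (4 and 7 adjusted over the list alone). BBX20 (AT4G39070) fell from 589 ± 7.1 to 99.3 ± 4.0 (-2.56, SE 0.20, adjusted p = 0.000608), BBX25 (AT2G31380) rose by 3.29, and ELIP1 (AT3G22840) had 3 reads in pifq against 502 in Col, a ratio of 186 (exact 95% interval 63.2 to 904, counting error only). By camera the adjusted p was 2.8e-12 for shade, 0.000159 for cell wall and 0.000219 for ethylene genes, with adjusted p = 0.357, 0.468 and 0.357 with an estimated correlation, and 0.0976 for light-signalling genes, and fry did not pass for cell wall genes (0.104). Without pifq replicate 1, the library high in seed storage transcripts, 7 shade, 5 cell wall and 5 light-signalling genes changed. Without Col replicate 1 the numbers were 5 cell wall, 2 ethylene and 5 light-signalling genes, without Col replicate 2 they were 6, 2 and 4, and without pifq replicate 2 ethylene had 2, while with DESeq2 1 ethylene gene rose and 7 fell.

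Most cell cycle transcripts were higher in pifq as well. Of 14 genes 9 rose (11 adjusted over the list alone; median 0.96), with HIK (AT1G18370) at 249 ± 19.9 in Col and 705 ± 16.7 in pifq (1.5, SE 0.20, limma adjusted p = 0.0064). Of 12 stomatal lineage and guard cell markers 4 rose (5 rose and 1 fell adjusted over the list alone), including SDD1 (AT1G04110), a protease of stomatal patterning, from 104 ± 5.2 to 392 ± 12.3 (1.90, SE 0.22, adjusted p = 0.00363). Of 14 root cell markers 0 changed with limma, 3 had an unadjusted p under 0.05, and edgeR called 0 and DESeq2 2. Of 16 abscisic acid response genes 5 fell (6 adjusted over the list alone), of 35 auxin response genes 2 rose and 3 fell (2 and 7), and of 13 gibberellin genes 2 rose and 1 fell (2 and 2). Camera adjusted p was 1.1e-09 for cell cycle, 0.00364 for stomatal, 0.000201 for abscisic acid and 0.00142 for auxin response genes, with adjusted p = 0.357, 0.357, 0.357 and 0.566 with an estimated correlation, and 0.273 for gibberellin genes, and fry did not pass for abscisic acid (0.0775) or auxin response genes (0.191). In the order cell cycle, stomatal, abscisic acid, auxin and gibberellin, the changed genes numbered 4, 3, 1, 2 and 0 without Col replicate 1, and 1, 1, 1, 0 and 0 without Col replicate 2. They numbered 1, 1, 1, 0 and 1 without pifq replicate 1, in which seed storage transcripts were high, and 5, 2, 1, 2 and 0 without pifq replicate 2. Of the auxin response genes 2 rose and 6 fell with library totals, and 2 rose and 7 fell with DESeq2.

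Among the largest changes in pifq, LOX2 (AT3G45140), a lipoxygenase of jasmonate synthesis, rose from 32.9 ± 26.5 to 3298 ± 286 (6.87, SE 0.50, limma adjusted p = 0.000442). AOC2 (AT3G25770) of the same pathway rose from 21.1 ± 13.4 to 714 ± 147 (5.15, SE 0.60, adjusted p = 0.00387), QQS (AT3G30720) from 3.3 ± 2.8 to 597 ± 135 (7.28, SE 0.59, adjusted p = 0.000787) and CRK30 (AT4G11460) by 3.90. GRF7 (AT5G53660), a growth-regulating factor, fell from 3187 ± 303 to 88.4 ± 12.7 (-5.16, SE 0.18, adjusted p = 1.7e-05), and CYP96A5 (AT2G21910) and FLP1 (AT4G31380) fell by 5.59 and 5.38. The B-box gene bbx23 (AT4G10240) had 1 read in pifq against 1233 in Col, a ratio of 1369 (exact 95% interval 245 to 54134, counting error only). XTH6 (AT5G65730) and MEE47 (AT4G00950) rose by 6.64 and 3.46, with adjusted p = 0.056 and 0.0664 without pifq replicate 1 and 0.074 and 0.0567 without pifq replicate 2. Of the 20581 genes, 742 rose and 591 fell, 1048 of them at least 2-fold. The changed genes numbered 396 without Col replicate 1, 428 without Col replicate 2, 365 without pifq replicate 1 and 568 without pifq replicate 2, and 2343 with DESeq2.

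The direct comparison of the mutants tests where their effects differ, without the Col libraries in the contrast. Photosynthesis genes separated them: 19 of 20 antenna genes, all 26 photosystem genes and 14 of 19 Calvin cycle genes were higher in pifq than in f1f3 by that test (19, 26 and 16 adjusted over the list alone), with median log2 differences of 4.58, 3.46 and 1.82. LHCA1 (AT3G54890) stood at 58656 ± 12086 in pifq and 1113 ± 423 in f1f3 (5.76, SE 0.30, limma adjusted p = 4.9e-05), and PSBO2 (AT3G50820) at 10016 ± 553 and 572 ± 132 (4.15, SE 0.20, adjusted p = 3.6e-05). Of 26 chlorophyll genes 21 were higher and 1 lower (23 and 1 adjusted over the list alone), with CHLH (AT5G13630) higher by 3.09, and of 12 carotenoid genes 6 were higher (8 adjusted over the list alone), with PSY (AT5G17230) higher by 2.09. PIL1 (AT2G46970), XTH15 (AT4G14130) and ATHB2 (AT4G16780) were lower in pifq, at -6.61, -4.59 and -2.39, within 11 lower and 3 higher of 27 shade and PIF-induced genes (17 and 4 adjusted over the list alone). PIF4 (AT2G43010) was higher in pifq by 3.05 and the lipase-like gene TLL1 (AT1G45201) by 7.11, while LATE (AT5G48890) and RD20 (AT2G33380) were lower, at -5.97 and -5.71. LHCB1.4 and LHCB1.1 were higher by 9.73 and 8.06 and LHCB1.2 (AT1G29910) and LHCB2.2 (AT2G05070) by 6.82 and 6.51, all copies that can share reads. The gene bbx23 had 1 read in pifq against 402 in f1f3, and ELIP1 had 3 against 556. Of 14 cell cycle genes 0 differed with limma, 3 had an unadjusted p under 0.05, and edgeR called 0 and DESeq2 1. Tested with camera, the adjusted p was 3.6e-22, 1.2e-25, 4.1e-11, 6.6e-13, 2.4e-05 and 0.000126 for antenna, photosystem, Calvin cycle, chlorophyll, carotenoid and shade genes, with adjusted p = 0.382, 0.382, 0.423, 0.382, 0.382 and 0.432 with an estimated correlation. In all, 1927 genes were higher and 1364 lower in pifq, a split that became 1521 and 1894 with library totals, where the median of all genes moved to -0.15. Without f1f3 replicate 1, f1f3 replicate 2, pifq replicate 1 or pifq replicate 2, the changed genes numbered 2032, 1388, 1956 and 1403 and the carotenoid genes 4, 2, 3 and 3, with chlorophyll genes at 14 without f1f3 replicate 2 and shade genes at 8 without pifq replicate 1.

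**Figure D2:**
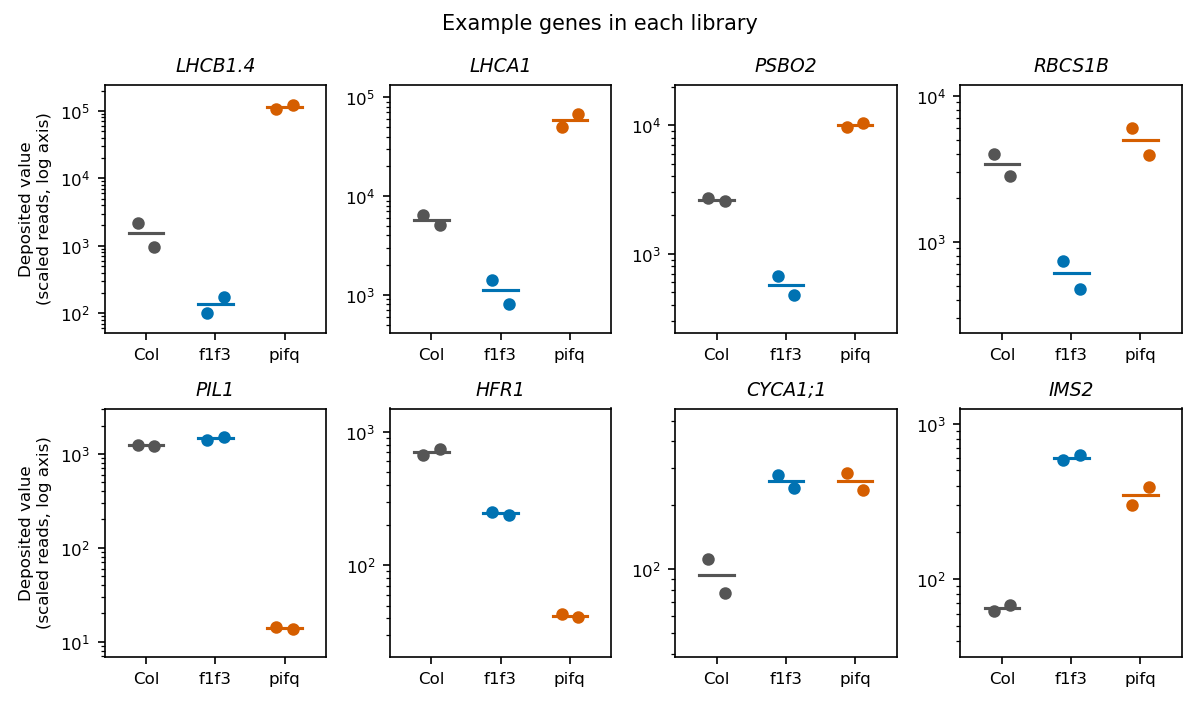
Deposited values (scaled reads, log axis) of 8 example genes in each library, where points are libraries and lines are group means. LHCA1 stood at 1113 in f1f3, 5766 in Col and 58656 in pifq.

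**Figure D3:**
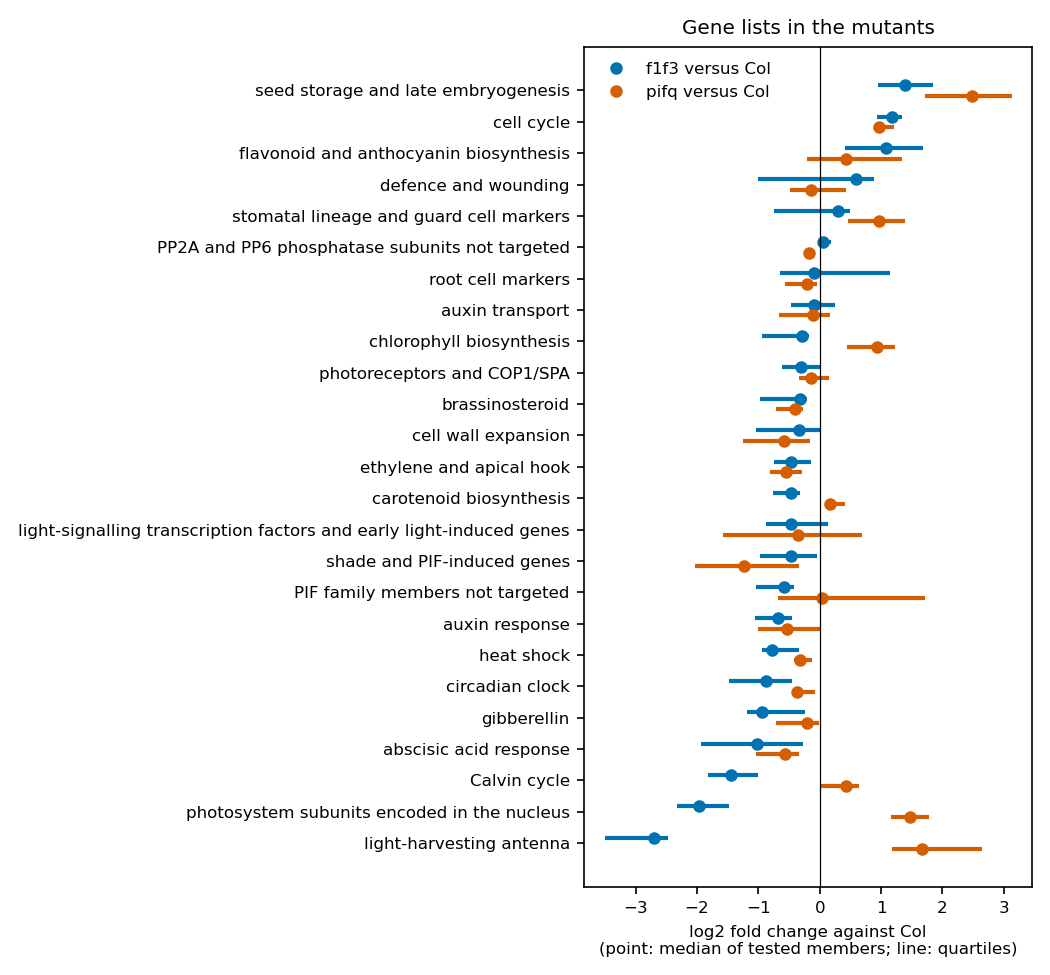
Median log2 fold change against Col of the tested members of 25 gene lists (points) with the quartiles (lines), in f1f3 (blue) and pifq (orange). The antenna median was -2.71 in f1f3 and 1.67 in pifq, and the medians of auxin transport and root markers (f1f3) and of heat shock (pifq) changed sign under other scalings.

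Genes that changed the same way in both mutants numbered 543, of which 313 rose and 230 fell. CYP96A12 (AT4G39510) rose from 47.8 ± 20.3 to 305 ± 24.1 in f1f3 and 377 ± 11.9 in pifq, IMS2 (AT5G23020) by 3.18 and 2.37, NAC044 (AT3G01600) by 2.95 and 2.27, and IMD1 (AT5G14200), an isopropylmalate dehydrogenase, by 2.93 and 2.14 on the log2 scale. IPMI2 (AT2G43100) and CYP83A1 (AT4G13770) rose by 2.03 and 3.32 in pifq. BCAT-2 (AT1G10070), a branched-chain aminotransferase, fell from 1947 ± 868 to 39.5 ± 8.6 in f1f3 and 233 ± 191 in pifq, and BBX17 (AT1G49130) from 1981 ± 477 to 243 ± 105 and 433 ± 104. BETA-TIP (AT1G17810), COR413IM1 (AT1G29395), WRKY49 (AT5G43290) and FLA13 (AT5G44130) fell by 2.40, 2.35, 2.26 and 2.07 in pifq. Independent lists of these sizes would share 85.9 rises and 75.6 falls. The simulated unchanged groups shared 0.44 genes on average and 3 at most. Since no gene was changed in them, few could pass. These numbers therefore cannot tell how much of the 543 comes from the shared Col libraries. In opposite directions, 98 genes fell in f1f3 and rose in pifq (independent lists 95.0). Another 20 rose in f1f3 and fell in pifq (68.5). All 118 differed in the direct test, which opposite calls bring about by construction, since the comparisons share 1 fit. Of the 543 genes, 75 differed in the direct test. Across genes, which are not independent replicates, the log2 fold changes had Pearson r = 0.38 and Spearman rho = 0.462. Simulated unchanged groups gave r = 0.505 from the shared Col libraries alone, with a covariance of 0.0855 against 0.283 observed. The simulation treats the libraries as independent. With a different Col library for each mutant, a split that also sets libraries of different replicate numbers side by side, r was 0.231 or 0.169 and the covariance 0.193 or 0.148. No Col library is shared in that split, so a shared library does not account for these covariances. A deviation that both Col libraries have in common would remain in them. The 2 Col libraries cannot be halved with a spread left in each part, so part of the observed excess can come from the Col libraries. The 543 genes became 132 without Col replicate 1, 116 without Col replicate 2, 225 without f1f3 replicate 2, 108 without pifq replicate 1 and 265 without pifq replicate 2, and 1071 with DESeq2. In pifq, the adjusted p of CYP83A1, BETA-TIP, COR413IM1, WRKY49 and FLA13 was 0.0567, 0.185, 0.0668, 0.119 and 0.133 without Col replicate 1, and 0.187, 0.163, 0.0526, 0.132 and 0.0978 without pifq replicate 1. Without Col replicate 2 it was 0.0523 for IPMI2, 0.08 for BCAT-2, 0.0506 for BBX17, 0.138 for BETA-TIP, 0.0646 for COR413IM1 and 0.0933 for WRKY49. Without pifq replicate 2 it was 0.0521 for BBX17, 0.14 for CYP83A1, 0.147 for BETA-TIP, 0.079 for WRKY49 and 0.12 for FLA13, and IPMI2 had 0.0859 without pifq replicate 1. CYP83A1 had 0.075 and 0.0777 without f1f3 replicate 1 or 2, and 0.0525 with edgeR, and in f1f3 CYP83A1 and FLA13 had 0.0821 and 0.0663 without f1f3 replicate 2.

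**Figure D4:**
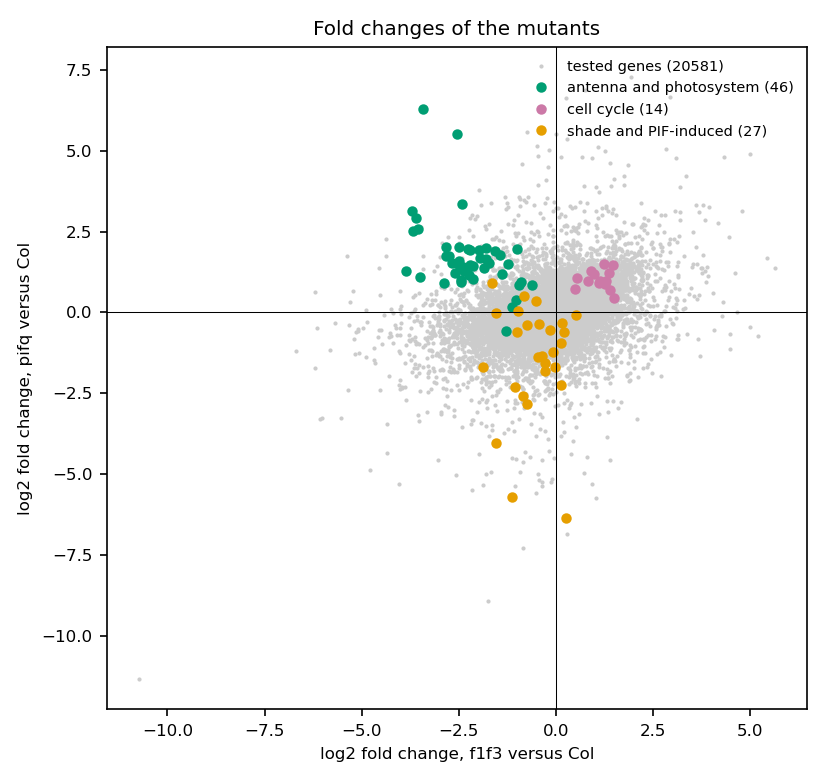
Log2 fold change against Col in f1f3 (horizontal) and in pifq (vertical), where each point is a gene of the 20581 tested and colours mark 46 antenna and photosystem, 14 cell cycle and 27 shade and PIF-induced genes. The antenna and photosystem genes lie mostly at upper left and the cell cycle genes at upper right.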

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

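The direct comparison of the mutants, camera and fry were planned, and the weighing of the 3 patterns below, with every test used in it, was chosen after the results were seen.

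In 5 gene lists of at least 5 tested genes the medians against Col lay on opposite sides of 0 in the mutants, and at least as many genes differed between the mutants as did not, with higher values in pifq than in f1f3. The median log2 difference was 4.58 for light-harvesting antenna genes, 3.46 for photosystem genes, 1.82 for Calvin cycle genes, 1.16 for chlorophyll biosynthesis genes and 0.75 for carotenoid biosynthesis genes. None of these lists passed camera with an estimated correlation (adjusted p = 0.382, and 0.423 for Calvin cycle genes). With fry the 5 lists passed, at adjusted p = 0.0126, 0.0181, 0.0221, 0.0126 and 0.0125 in the order given. The lists were picked by calls in this same comparison, which makes a pass likely, so fry gives no separate support here. Of 12 stomatal genes 4 were also higher in pifq (median 0.90; camera adjusted p = 0.00532, adjusted p = 0.382 with an estimated correlation, and fry 0.0919), but their medians against Col were above 0 in both mutants. In addition, 118 genes changed in opposite directions against Col, which fixes in advance that they differ in the direct test. Of these, 98 fell in f1f3 and rose in pifq, where independent lists would share 95.0. The other 20 rose in f1f3 and fell in pifq, where independent lists would share 68.5.

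By their medians, antenna and photosystem transcripts were lower in f1f3 and higher in pifq than in Col, and fry gave adjusted p = 0.0406 and 0.0511 for the antenna list and 0.0556 and 0.0775 for the photosystem list, so that it passed only for antenna genes in f1f3. The scaling of the libraries is argued against, since over 5 scalings the median of the 46 genes was at most -2.121 in f1f3 and at least 1.483 in pifq. Reads shared between near-identical copies are argued against as well, since the genes outside the LHCB1 and LHCB2 families had medians of -2.168 and 1.463. Stray light on pifq does not match the median of -3.082 (median SE 0.5269) of ELIP1, ELIP2, HY5 and CHS, although it was not tested whether pifq can still induce these genes. Stray light on Col but not on f1f3 stays open, since the same genes had a median of -0.142 in f1f3, and the genotypes, which the design names, stay an untested explanation.

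Cell cycle transcripts were higher in both mutants than in Col. The scaling of the libraries is argued against, since the median of the list lay between 0.9537 and 1.329 under all scalings. A larger share of root tip tissue in pifq is argued against by 5 root tip genes with a median of -0.005467 (SD 0.2853), while in f1f3 their median of -0.01138 had an SD of 0.9649 and leaves it open. A chance low in the shared Col libraries had no separate test. Fry, which sets the list against the spread between libraries, gave adjusted p = 0.03319 in f1f3 and 0.03944 in pifq. The rise thus exceeded that spread at the threshold, but both values test the rise itself and use the same Col libraries. Camera, which sets the list against other genes, did not pass with an estimated correlation (adjusted p = 0.45 and 0.357 with an estimated correlation). The genotypes stay a hypothesis, and a condition other than genotype that both Col libraries share was not tested.

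PIF1 and PIF4 were not reduced in pifq at the level of transcripts. A Col library mislabelled as pifq is argued against, since PIF3 in the higher of the pifq libraries was 3.508% of the lower Col library. PIF3 cannot show whether the pifq plants carry the pif1 and pif4 mutations, which was not tested. In f1f3 FYPP1 and FYPP3 transcripts were reduced but present, at 336 and 272. Whether the mutant alleles of either mutant make transcripts without function was not tested, because the files hold a single value per gene.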

How the results depend on the processing

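The edgeR test with TMM factors, the limma fits with TMM or library totals and the other pseudocounts were chosen after the data were seen, and the rest were planned, of which edgeR with RLE factors or library totals and DESeq2 were run on recovered reads. Among 270 named results, none passed in both the reported fit and an alternative with opposite signs. A change of sign without a pass was not counted as a reversal. The 270 include targeted genes that did not pass in the reported fit. With a library left out in turn, many of the results no longer passed. For f1f3 against Col, the 5018 changed genes became 3213 at 2-fold or more, 1500 at adjusted p below 0.01, and 1422 (without f1f3 replicate 2) to 4663 (without pifq replicate 1) with a library left out. For pifq against Col, the 1333 became 2343 with DESeq2, 304 at adjusted p below 0.01, and 365 (without pifq replicate 1) to 1233 (without f1f3 replicate 1). For pifq against f1f3, the 3291 became 1209 at adjusted p below 0.01, and 1388 (without f1f3 replicate 2) to 2859 (without Col replicate 1). The 543 shared genes became 1071 with DESeq2, 343 at 2-fold or more, 60 at adjusted p below 0.01, and 108 (without pifq replicate 1) to 455 (without f1f3 replicate 1). The correlation of the mutants ran from 0.302 (without pifq replicate 1) to 0.46 (without Col replicate 1). Stricter thresholds lower counts by construction. Fewer libraries lowered the counts of this paragraph but need not do so. With only the 4 libraries compared, the photosystem genes that rose in pifq went from 12 to 20. For DESeq2 the cause was not tested. On recovered reads, edgeR with TMM factors gave 4951, 1375, 3236 and 564 genes. Library totals in place of the deposited scaling ended 18 named results with limma and 19 with edgeR, and moved 12 of 66 list counts with each. Of the 75 list tests, fry lost 18 and gained 1, and the estimated correlation lost 35. Depth limits the genes with few reads, whose ratios have the wide intervals given.

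Replicate numbers left a pattern in the values: component 3 (15.8% of the variance) set replicate 1 apart from replicate 2 in every group, and the residuals of the groups had r = 0.345, 0.444 and 0.215. With a replicate block the changed genes numbered 7436 in f1f3, 2915 in pifq and 5458 between the mutants, 1468 were shared, and 26 of 66 list counts moved. The labels do not say whether replicates with the same number were grown or handled together, so the block was not used for the reported values, and the cause was not tested.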

Other observations

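The tests on the 4 later gene lists were written before their results were seen but after the largest changes had been seen, and the genes changed most in both mutants were chosen after their values were seen.

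Smaller gene lists in f1f3 held single genes that changed against Col. Of 13 circadian clock genes 3 fell (3 adjusted over the list alone; median -0.88), such as ELF3 (AT2G25930), a component of the evening complex, from 2625 ± 566 to 1152 ± 149 (-1.18, SE 0.20, limma adjusted p = 0.00703), and PRR5 (AT5G24470), a pseudo-response regulator, at -1.73. Of 9 brassinosteroid genes 3 fell (3 adjusted over the list alone), led by BAS1 (AT2G26710), which inactivates the hormone, at -1.05. Of 12 stomatal and guard cell genes 1 rose and 2 fell (1 and 2 adjusted over the list alone): SDD1 (AT1G04110) rose from 104 ± 5.2 to 348 ± 66.7, and the potassium channel KAT1 (AT5G46240) fell by 1.56. Of 12 flavonoid genes 3 rose (3 adjusted over the list alone; median 1.08), among them CHI (AT3G55120) by 1.47, with adjusted p = 0.0681 without f1f3 replicate 2. Of 15 photoreceptor and COP1/SPA genes 3 fell (3 adjusted over the list alone), of 15 auxin transport genes 2 fell (1), of 18 light-signalling genes 1 rose and 1 fell (0 and 1), of 11 defence genes 2 rose and 1 fell (3 and 2), and of 8 further PP2A and PP6 subunit genes 1 fell (0). PIF8 (AT4G00050), 1 of 3 further PIF family genes (1 adjusted over the list alone), fell from 219 ± 26.4 to 78.2 ± 22.6, with adjusted p = 0.0544 without f1f3 replicate 2. Of 9 seed storage and 7 heat shock genes 0 changed with limma; 0 and 1 had an unadjusted p under 0.05, edgeR called 0 of each, and DESeq2 0 and 1. The camera test gave adjusted p = 0.0122, 0.0266 and 0.0232 for clock, brassinosteroid and flavonoid genes, with adjusted p = 0.45, 0.468 and 0.594 with an estimated correlation, and the other lists did not pass. Fry did not pass for clock (0.07), brassinosteroid (0.0624) or flavonoid genes (0.192). Brassinosteroid and flavonoid genes had camera adjusted p = 0.0917 and 0.0637 without f1f3 replicate 2, and brassinosteroid genes 0.0697 without Col replicate 1. In the order photoreceptor, auxin transport, light-signalling, defence and PP2A, the changed genes numbered 2, 1, 0, 0 and 0 without Col replicate 1, 0, 1, 2, 3 and 0 without Col replicate 2, 2, 3, 3, 1 and 0 without f1f3 replicate 1, and 0, 0, 0, 1 and 0 without f1f3 replicate 2. Without pifq replicate 1 or 2, flavonoid genes numbered 5 and 5, PP2A genes 0 and 0, defence genes 1 and 2 and auxin transport genes 2 and 1. Without f1f3 replicate 1 or 2 flavonoid genes numbered 1 and 0, and brassinosteroid genes 3 and 1. With library totals 1 photoreceptor gene and 0 PP2A genes fell, and with DESeq2 5 clock genes fell.

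In pifq, PIF7 (AT5G61270), a PIF that acts in shade, rose from 12.2 ± 1.1 to 143 ± 59.7 (3.39, SE 0.52, limma adjusted p = 0.011), with 0.0744 without pifq replicate 2. PIF6 (AT3G62090) fell from 364 ± 15.6 to 145 ± 58.8, with adjusted p = 0.117, 0.131 and 0.14 without Col replicate 1, Col replicate 2 or pifq replicate 1, so 1 of 3 further PIF family genes rose and 1 fell (1 and 1 adjusted over the list alone). Of 11 defence genes LOX2 rose (1 adjusted over the list alone). Of 9 brassinosteroid genes 2 fell (4 adjusted over the list alone), of 15 auxin transport genes 2 fell (1 rose and 5 fell), and of 12 flavonoid genes 1 rose (2 rose and 1 fell). Camera passed for brassinosteroid genes (adjusted p = 0.00672; adjusted p = 0.357 with an estimated correlation; fry 0.0656). With limma 0 photoreceptor, seed storage, heat shock, clock and PP2A genes changed; 4, 0, 0, 0 and 1 had an unadjusted p under 0.05, edgeR called 1, 0, 0, 0 and 0, and DESeq2 2, 2, 0, 0 and 0. The seed storage list had a median of 2.48, and pifq replicate 1 held most of its reads. In the order brassinosteroid, auxin transport and flavonoid, the changed genes numbered 0, 0 and 0 without Col replicate 1, 0, 2 and 0 without Col replicate 2, 0, 1 and 0 without pifq replicate 1, and 0, 0 and 2 without pifq replicate 2. With DESeq2 1 auxin transport gene rose and 5 fell, and 2 flavonoid genes rose and 1 fell.

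Between the mutants, ELIP2 (AT4G14690) and BBX20 (AT4G39070) were lower in pifq by the direct test, at -3.82 and -2.11, and GLK2 (AT5G44190), a regulator of chloroplast development, was higher by 1.24, within 5 higher and 5 lower of 18 light-signalling genes (8 and 6 adjusted over the list alone). EXPA18 (AT1G62980) was lower in pifq, at -2.71, within 1 higher and 4 lower of 14 root markers (1 and 4), and TMM (AT1G80080), a receptor of stomatal patterning, was higher by 1.36 within 4 higher of 12 stomatal genes (6). GASA6 (AT1G74670), ACO4 (AT1G05010), XTH24 (AT4G30270), LAX1 (AT5G01240) and COR47 (AT1G20440) were higher in pifq by 4.63, 3.15, 2.43, 1.74 and 1.68, and JAZ1 (AT1G19180) was lower, at -1.55. Higher and lower genes numbered 4 and 1 of 13 for gibberellin (6 and 2 adjusted over the list alone), 1 and 3 of 14 for ethylene (1 and 3), 3 and 7 of 24 for cell wall (5 and 7), 3 and 2 of 16 for abscisic acid (3 and 2), 3 and 1 of 35 for auxin response (2 and 1) and 1 and 0 of 15 for auxin transport (3 and 4). They numbered 2 and 3 of 11 for defence (2 and 3), 3 and 0 of 13 for clock (3 and 0), 2 and 0 of 15 for photoreceptors (2 and 1), 1 and 1 of 9 for brassinosteroid (1 and 1), 0 and 1 of 12 for flavonoid (0 and 0), 3 and 1 of 6 for targeted (3 and 2) and 2 and 0 of 3 for further PIF family genes (2 and 1). With limma 0 seed storage, heat shock and PP2A genes differed; 0, 1 and 1 had an unadjusted p under 0.05, edgeR called 0, 0 and 0, and DESeq2 4, 1 and 0. Camera passed for stomatal genes (adjusted p = 0.00532; adjusted p = 0.382 with an estimated correlation; fry 0.0919) and for none of the other lists of this paragraph, and the medians of light-signalling, photoreceptor, auxin response, brassinosteroid and abscisic acid genes changed sign under other scalings. In the order light-signalling, root, stomatal, gibberellin, ethylene, cell wall and abscisic acid, the changed genes numbered 6, 3, 2, 4, 1, 7 and 3 without f1f3 replicate 1, 4, 1, 2, 2, 3, 6 and 1 without f1f3 replicate 2, 7, 2, 2, 1, 4, 6 and 2 without pifq replicate 1, and 5, 3, 1, 1, 1, 6 and 2 without pifq replicate 2. For auxin response, auxin transport, defence, clock, photoreceptor, brassinosteroid, flavonoid, targeted and PIF family genes they numbered 4, 2, 3, 1, 0, 1, 0, 3 and 2 without f1f3 replicate 1, 3, 1, 2, 0, 0, 0, 0, 2 and 1 without f1f3 replicate 2, 2, 1, 2, 1, 1, 1, 3, 4 and 2 without pifq replicate 1, and 3, 1, 3, 0, 0, 0, 0, 2 and 2 without pifq replicate 2. Brassinosteroid had 1 without Col replicate 1 or 2. Auxin transport had 1 higher and 5 lower genes with library totals and 2 and 3 with DESeq2, flavonoid had 2 lower with DESeq2, and stomatal had 2 higher with edgeR and library totals.

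Genes of methionine-derived (aliphatic) glucosinolate synthesis, such as IMS2, were among the largest shared rises, so the other genes of the pathway were tested. Whether the pathway is over-represented among all 313 shared rises was not tested. In f1f3, 7 of 11 rose, including CYP79F2 (AT1G16400) from 8.8 ± 3.9 to 174 ± 42.1 and MYB28 (AT5G61420), a regulator of the pathway, by 1.62, with a list median of 1.126, consistent with a rise of the pathway. In pifq 3 of 11 rose, MYB28 by 2.36, CYP79F2 by 2.76 and GSTU20 (AT1G78370) by 1.37, with a list median of 1.37, which leaves the question open because 8 of the genes did not pass. Indolic glucosinolate genes had a median of 0.6665 in f1f3, where 2 of 9 rose, which leaves a rise open. In pifq their median was -0.006832 and 0 of 9 changed with limma (1 with unadjusted p under 0.05, 0 with edgeR and 0 with DESeq2), which argues against one. Camera adjusted p over the 4 lists was 0.000145 in f1f3 and 0.000127 in pifq for the aliphatic list, with adjusted p = 0.144 and 0.128 with an estimated correlation. Without Col replicate 1, Col replicate 2, f1f3 replicate 1 or f1f3 replicate 2, 5, 3, 4 and 2 aliphatic and 1, 1, 0 and 1 indolic genes rose in f1f3, and without pifq replicate 1 or 2, 1 and 2 aliphatic genes rose in pifq. Without Col replicate 1, 2 aliphatic genes rose in pifq, and 4 indolic genes rose in f1f3 with library totals or DESeq2. Between the mutants 0 aliphatic genes differed with limma (3 with unadjusted p under 0.05, 1 with edgeR and 1 with DESeq2). By the direct test 3 indolic genes were lower in pifq, or 0, 1, 2 and 1 without f1f3 replicate 1, f1f3 replicate 2, pifq replicate 1 or pifq replicate 2.

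ASN1, BCAT-2 and THA1, which respond to sugar starvation, were among the largest falls in f1f3, so other starvation genes were tested. In f1f3, 14 of 15 fell, such as DIN10 (AT5G20250) from 9451 ± 960 to 1139 ± 67.1 (-3.05, SE 0.18, limma adjusted p = 0.000672) and ERD5 (AT3G30775), a proline dehydrogenase, at -2.91, with a list median of -2.023, consistent with a lower starvation response. In pifq SEN1 (AT4G35770) and ERD5 fell, at -1.99 and -1.13, with a list median of -0.4671, which leaves the question open. By the direct test 11 of 15 were higher in pifq. For the starvation list camera gave adjusted p = 4.5e-11 in f1f3 and 0.000127 in pifq, with adjusted p = 0.203 and 0.526 with an estimated correlation. With DESeq2 4 starvation genes fell in pifq. Sugar content was not measured. LOX2 and AOC2 were among the largest rises in pifq, yet of 12 other jasmonate biosynthesis genes 0 rose and ACX1 (AT4G16760) fell, with a median of -0.3364, which argues against a rise of the whole pathway (1 rose and 2 fell with DESeq2). In f1f3, AOC3 (AT3G25780) rose by 0.77 and LOX4 (AT1G72520) fell by 1.86, and the changed genes of the list numbered 0 without Col replicate 1 and 1 without Col replicate 2, f1f3 replicate 2, pifq replicate 1 or pifq replicate 2. Between the mutants 2 jasmonate genes were higher and 2 lower in pifq, with totals of 2, 2, 2 and 0 without f1f3 replicate 1, f1f3 replicate 2, pifq replicate 1 or pifq replicate 2. Without Col replicate 1, Col replicate 2, pifq replicate 1 or pifq replicate 2, the falls in pifq numbered 2, 1, 1 and 2 for starvation and 0, 0, 0 and 0 for jasmonate genes (2 and 2 without f1f3 replicate 1 or 2), and without f1f3 replicate 2 or pifq replicate 2, 3 and 5 starvation genes were higher in pifq than in f1f3.

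A few genes went from present to near absent, or the reverse, in both mutants: 5 genes changed the same way by a log2 fold change of at least 4 in each. Only AT3G28915 stood high in any group. AT3G28915, a pseudogene in the name table, stood at 4422 and 5710 in the Col libraries, 2.1 and 1.8 in f1f3 and 0.8 and 1.1 in pifq. The fall was -10.74 in f1f3 (limma adjusted p = 4.2e-05), and in pifq it had 2 reads against 9966 in Col, a ratio of 5534 (exact 95% interval 1532 to 45706, counting error only). AT3G29120, also a pseudogene, stood at 1.3 and 2.6 in Col, 80.5 and 104 in f1f3 and 82.2 and 87.4 in pifq (5.0 and 4.90). AT3G28315 had 105 reads in Col against 3 in f1f3 and 2 in pifq, ratios of 38 (12.6 to 187) and 58.3 (15.7 to 488). NDB4 (AT2G20800), a mitochondrial NADH dehydrogenase, had 2 reads in Col against 78 in f1f3 and 125 in pifq, ratios of 35.9 (9.62 to 302) and 56.3 (15.3 to 470). AT5G44255 had 76 reads in Col against 3 in f1f3, a ratio of 27.5 (9.06 to 136), and 0 in pifq, at least 28.1-fold lower. Whether the mutants carry DNA of another accession or of a common parent at these loci was not tested, so these values are not read as effects of the mutated genes.

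Chloroplast-encoded genes took 4.15% and 2.60% of the reads of the Col libraries, 1.76% and 2.05% in f1f3 and 2.83% and 2.22% in pifq. Of 117 such genes tested 1 rose and 7 fell in f1f3 (median -0.63), 1 rose in pifq (-0.22) and 4 were higher in pifq than in f1f3. Of 63 mitochondrial genes 1 rose in f1f3 (median 0.47), 0 changed in pifq (limma; 1 with unadjusted p under 0.05) and 1 was lower in pifq than in f1f3.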
